A study of Mus musculus with 2 samples.

How the data were processed

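Expression profiles of mouse peritoneal macrophages were used, with 1 array per condition. Per the labels, the cells came from C57BL/6J mice and were collected 3 days after an injection of thioglycolate, an irritant that draws macrophages into the peritoneal cavity. One culture received LPS+CPN and the other LPS+CPN+GGOH. LPS is lipopolysaccharide and GGOH is geranylgeraniol, the alcohol form of a mevalonate-pathway isoprenoid; the compound named CPN is given in the labels by this abbreviation alone. Dose and duration of treatment, and whether the cultures were made from the same animals, are not given in the sources used here. Total RNA was extracted with a spin-column kit and labelled as biotinylated cRNA, per the labels' protocols.

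The deposited table held 1 signal intensity per probe set and array on a linear scale, for 45101 probe sets including 64 control probe sets. The submitters' processing notes name MAS5, an algorithm that reduces the probes of a probe set to 1 background-corrected signal; its version and scaling target are not given in the sources used here. The mean signal of the central 96% of probe sets was 500.0 on each array, so the deposited intensity values had already been brought to a common level. Detection calls were not used here. Single low signals could not be told from background, and the number of arrays limits the precision.

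Probe sets were named with the platform's gene annotation. Of 45037 non-control probe sets, 34945 had 1 gene symbol (77.6%), 932 had several and 9160 had no gene listed. The gene identifiers of 34741 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. Control probe sets and 2038 probe sets of the _x_at class, which can cross-hybridize with other transcripts, were left out of the gene values. This left 32907 probe sets of 18093 genes. Probe sets with several genes or no listed gene were kept apart and only counted.

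A floor was set at the 50th percentile of the pooled non-control signals of both arrays, a signal of 59.9. A gene at the floor on both arrays was not measured. A gene at the floor on 1 array had only a bound, given as "at least" a fold against the floor. Each gene took the value of its probe set with the highest mean log2 signal, and its log2 ratio was the LPS+CPN+GGOH value minus the LPS+CPN value. Genes were counted as higher or lower at 2-fold or more, bounds included. There is no replicate, so there is no test, standard error or p-value for any gene. As a scale of error within the arrays, the pooled SD of log2 ratios between probe sets of the same gene was computed over 4166 genes with 10774 probe sets. It was 0.45, with a median SD of 0.32.

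For 38 gene lists fixed in advance, the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these arrays and carries no p-value. Lists with under 3 measured members were not summarised. Another 7 lists were written after the main comparison was seen, before their medians were computed: further fibroblast, mesothelial, leukocyte and macrophage, cell cycle and unrelated lineage genes, YAP and TEAD targets, and interferon-gamma-type genes. Serpinh1 of the fibroblast list and Wt1 and Slpi of the mesothelial list had values already seen, so these medians were also computed without them. The genes named in the text followed a rule fixed in advance. It took, per direction, the 10 largest log2 ratios among genes measured on both arrays, at least 2-fold apart, with the same sign in all measured probe sets. It added the 3 brightest genes per direction known only by a bound of at least 2-fold, and up to 4 members of each list with the largest ratios. Rhob, Rac1, Il1b, Tnf, Il6, Il10, Il12b, Nos2, Ptgs2 and Klf2 were always named. Some other genes that the rule names, and 1 of the gene lists, are not reported here. Other genes are named where a count is small or a point needs them, and these were chosen after their values were seen.

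In addition, 8 other settings were chosen before the data were examined. They were division of each array by its median, quantile normalization, a lowess of the log2 ratio on mean signal (span 0.4), floors at the 25th and 75th percentiles, a pseudocount equal to the floor in place of it, the median over a gene's probe sets, and _x_at probe sets kept. Another scaling, which set the macrophage markers to a median log2 ratio of 0, was added after the data were seen. A single value or list median was taken as moved when it shifted by more than the SD between probe sets of a gene, and a count when it changed by over 1.5 times.

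The steps were tested on simulated data for LPS+CPN+GGOH against LPS+CPN, with 10943 genes, noise of SD 0.15 on the log2 scale and 200 changed genes. At log2 changes of 1.5 and -1.5, 98% and 100% of the changed genes were recovered at 2-fold, and at 3 and -3 all of them were. This noise is smaller than the spread between probe sets of a gene, so the simulation checks the computation and gives no rate of false calls. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. Positions of probes along their transcripts were not analysed here.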

Results

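Gene expression was measured in thioglycolate-elicited peritoneal macrophages of C57BL/6J mice, on 1 array for cells treated with LPS+CPN and 1 array for cells treated with LPS+CPN+GGOH. The comparison asked which genes were higher or lower when geranylgeraniol (GGOH), an isoprenoid alcohol of the mevalonate pathway, was present with LPS+CPN. Each array gave signals for 45101 probe sets, and the median signal was 56.7 on the LPS+CPN array and 63.7 on the LPS+CPN+GGOH array. There were no replicates, so all differences describe these 2 arrays. The spread between probe sets of the same gene, an SD of 0.45 on the log2 scale, gives a measure of the error of a single ratio.

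The genes with the highest ratios on the LPS+CPN+GGOH array included several that encode proteins of the extracellular matrix or actin-binding proteins. Col1a2, a chain of type I collagen, was 38.9-fold higher, fibronectin (Fn1) 20.02-fold higher, and fascin (Fscn1), an actin-bundling protein, 73.4-fold higher. These are values of 1 probe set per gene. Over the measured probe sets, log2 ratios ranged from 0.88 to 5.83 for Col1a2, 2.86 to 4.32 for Fn1 and 1.02 to 6.20 for Fscn1. Among the lowest ratios were those of Klf2, a zinc-finger transcription factor that was 15.0-fold lower, of Irf1, a transcription factor of the interferon response (6.30-fold lower), and of the cytokine gene Tnf (5.44-fold lower). Rhob, which encodes a prenylated small GTPase, was 3.56-fold lower, and the cytokine gene Il6 was 5.67-fold higher. The same array showed 13 of 14 measured mesothelial cell and fibroblast markers at least 2-fold higher, and its RNA had relatively more 5' signal for Actb and Gapdh than the LPS+CPN array.

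Of 18093 genes, 11518 were measured on at least 1 array and 9909 on both. At 2-fold or more, 634 genes were higher with GGOH (5.50% of those measured) and 191 were lower (1.66%). Of the higher genes, 306 had only a bound because their signal on the LPS+CPN array was at the floor, against 40 of the lower genes. Large differences were nearly all in 1 direction, with 191 genes at least 4-fold higher and 8 at least 4-fold lower. Genes with several probe sets showed the same sign in all measured ones for 219 of 239 higher genes and 47 of 68 lower genes. A probe set at the floor on the LPS+CPN array can only count as higher or drop out. Part of the agreement among higher genes is therefore built in, and the shares do not compare the reliability of the directions. The median log2 ratio of all measured genes was -0.01, with quartiles at -0.28 and 0.29, and log2 signals correlated across genes with r = 0.965 (genes are not independent replicates). Higher genes made up 76.8% of those past 2-fold. This share depended on the scaling: it was 61.4% (529 higher, 332 lower) with arrays divided by their medians, which shifted the median of all genes by -0.17. It was 62.1% (503 higher, 307 lower) after quantile normalization. It was 92.3% (991 higher, 83 lower) when the arrays were scaled to equal macrophage markers, a choice made after the data were seen that shifted the median by 0.27. Of the genes named by rule, 9 that were at least 2-fold lower no longer were under equal macrophage markers (Rhoh, Nfkbie, Cish, Ifit1, Cmpk2, Panx1, Hspa1a, Birc3 and Ankrd37). With arrays divided by their medians 7 higher genes no longer passed 2-fold (Mrc1, Mt2, Asns, Hspb1, Rpl12, Itgam and Mmp8). With the median over a gene's probe sets Foxo3, Nfkbie, Cmpk2, Ncf1, Ptgs2 and Birc3 no longer did.

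**Figure D1:**
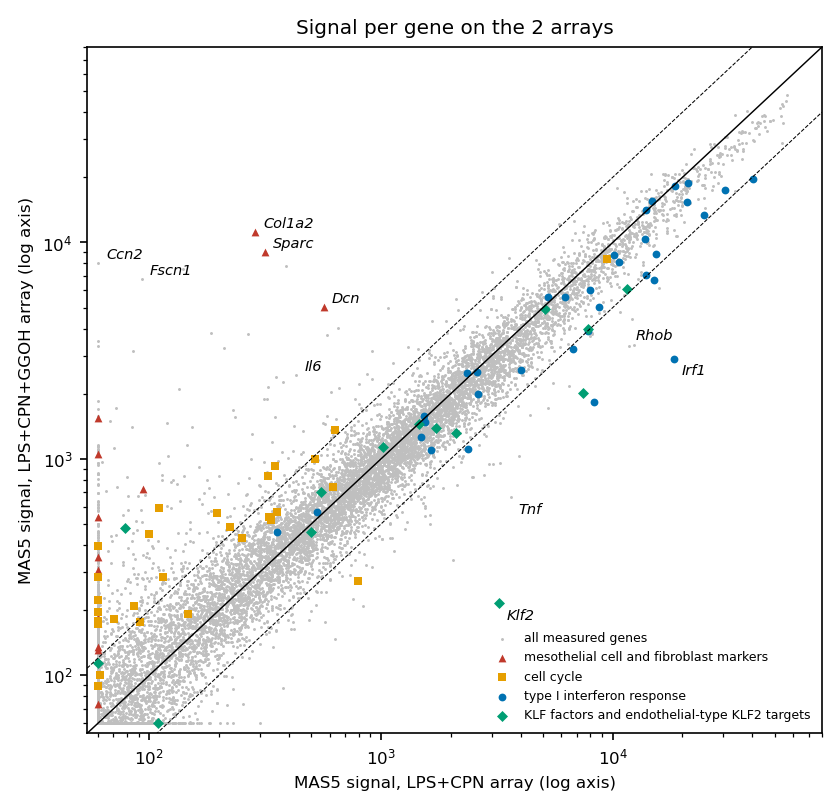
Signal per gene on the LPS+CPN array (x axis, MAS5 signal, log scale) against the LPS+CPN+GGOH array (y axis, same unit), with signals below the floor of 59.9 drawn at the floor, equality as a solid line and 2-fold differences as dashed lines. Colours mark 4 gene lists; Col1a2, Sparc and Dcn lie far above the diagonal, while Klf2, Tnf, Irf1 and Rhob lie below it.

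Among genes measured on both arrays with 1 sign in all probe sets, the 10 with the highest ratio were Fscn1 (signal 92.6 with LPS+CPN and 6797 with GGOH, log2 ratio 6.20), Cald1 (5.75), Col1a2 (5.28), Ptgis (5.21), Arhgap29 (4.59), Fbln2 (4.47), Bgn (4.37), Fn1 (4.32), Tead1 (4.06) and Tpm2 (3.99). Cald1 encodes caldesmon and Tpm2 a tropomyosin, both actin-binding proteins, while Fbln2 and Bgn encode the matrix proteins fibulin and biglycan. Ptgis is prostacyclin synthase, Arhgap29 a GTPase-activating protein and Tead1 a transcription factor of the Hippo pathway. Over a gene's measured probe sets, log2 ratios ranged from 1.18 to 5.75 for Cald1, 0.06 to 3.99 for Tpm2 and 4.37 to 5.14 for Bgn. The LPS+CPN signals of Fbln2 (67.5), Tpm2 (70.5) and Arhgap29 (71.6) lay just above the floor of 59.9. The brightest genes without a measured signal on the LPS+CPN array were Ccn2 (connective tissue growth factor), Serpinh1 (a collagen chaperone) and Ccn1. Ccn2 was at least 134-fold higher, Serpinh1 at least 58.6-fold and Ccn1 at least 55.5-fold.

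Mesothelial cell and fibroblast markers formed the list with the largest median, a log2 ratio of 2.75, which lay above all 10000 random lists of the same size and signal (highest 1.16). Besides Col1a2, the matrix genes Sparc (log2 ratio 4.83) and Dcn (3.16) were measured on both arrays; 1 of 3 Sparc probe sets was lower. Col3a1 was at least 25.9-fold higher and Col1a1 at least 17.6-fold higher. The mesothelial genes Wt1 and Msln were at least 9.02-fold and at least 3.07-fold higher. Only 4 of the 14 markers were above the floor on the LPS+CPN array, so most values are lower bounds.

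Genes of the actin cytoskeleton and targets of serum response factor were also higher, with 9 of 25 at least 2-fold higher, none lower, and a median of 0.52 (percentile 100). Tagln, a smooth muscle actin-binding protein, was at least 18.9-fold higher, and Acta2, smooth muscle actin, had a log2 ratio of 3.83. These genes moved together with the fibroblast markers. Fibronectin carried the alternative activation list, in which 2 of 15 genes were at least 2-fold higher (Fn1, and the mannose receptor gene Mrc1 at 1.06) and none lower. Its median of -0.13 (percentile 24.0) became 0.14 under equal macrophage markers. Arg1 had a log2 ratio of 0.64, and Ccl22 was at least 1.62-fold lower.

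In the other direction, the 10 lowest ratios among genes measured on both arrays, with 1 sign in all probe sets, were those of Klf2 (3222 with LPS+CPN and 215 with GGOH, log2 ratio -3.90), Irf1 (-2.66), Clic5 (-2.57), Tnf (-2.44), Ifi47 (-2.18), Slc40a1 (-2.11), Ubd (-2.00), Hcar2 (-1.94), Gbp7 (-1.88) and Klf4 (-1.87). Slc40a1 encodes the iron exporter ferroportin, Hcar2 the niacin receptor, and Ifi47 and Gbp7 encode interferon-inducible GTPases. The brightest genes at least 2-fold lower and above the floor only with LPS+CPN were Krtap12-1 (at least 5.02-fold lower), the RIKEN transcript 4933433H22Rik (at least 3.84-fold) and Eef2kmt (at least 3.60-fold). Among Krüppel-like factors and endothelial-type KLF2 targets, Klf2 and Klf4 were at least 2-fold lower and the thrombomodulin gene Thbd was higher (log2 ratio 2.61). Klf6 had a log2 ratio of -0.98. The median of the 14 genes was -0.22 (percentile 7.86) and became 0.05 under equal macrophage markers. With arrays divided by their medians 4 of the list were at least 2-fold lower, and after quantile normalization 3.

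Type I interferon response genes lay lower as a group, with 7 of 33 at least 2-fold lower, none higher, and a median of -0.41, below all random lists (percentile 0). Besides Irf1 and Ifi47, these were Ifit1 (-1.16), Cmpk2 (-1.09), Oas3 (-1.07), Rsad2 (-1.04) and Igtp (-1.01). The median kept its sign under every scaling, but the number at least 2-fold lower was 9 with arrays divided by their medians, 5 after quantile normalization, 4 after lowess and 2 under equal macrophage markers. Genes of negative feedback on inflammatory signalling had a median of -0.46 (percentile 0), with 4 of 26 at least 2-fold lower and none higher. They were Socs3 (-1.77), the anti-inflammatory cytokine gene Il10 (at least 2.69-fold lower), Nfkbie (-1.10) and Cish (-1.003). Under equal macrophage markers 2 of them passed 2-fold. Macrophage markers had a median of -0.27 on the same scale.

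Cytokine genes differed in both directions. Fibroblast markers were higher on the same array, and which cells carried the cytokine and chemokine signals was not tested. Of 21 inflammatory cytokines, 5 were at least 2-fold higher, namely Csf1 (log2 ratio 2.88), Il6 (5.67-fold), Lif (1.48), Il33 (at least 3.20-fold) and Csf3, known only by a bound. Tnf and Tnfsf9 (-1.42) were at least 2-fold lower, Il1b had a log2 ratio of -0.98 and Il12b one of -0.11. With arrays divided by their medians 4 were at least 2-fold lower. The median of -0.11 (percentile 14.8) became 0.16 under equal macrophage markers. Of 23 chemokines, 5 were at least 2-fold higher: Cxcl13 (2.48), Ccl7 (1.39), Cxcl1 (1.28), Cxcl5 (at least 7.63-fold) and Cxcl12 (at least 3.72-fold). Cxcl3 was lower (-1.12), though none of the list was 2-fold lower under equal macrophage markers, and the list's median of -0.02 (percentile 66.8) became 0.25 under equal macrophage markers.

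None of 23 genes of TLR4 signalling and NF-kB passed 2-fold at the deposited scaling; Ikbkg had a log2 ratio of -0.96, Rela -0.57, Tlr4 -0.56 and Traf6 -0.52. The list's median of -0.17 (percentile 10.7) became 0.10 under equal macrophage markers. Among 21 antimicrobial and oxidative burst genes (median -0.27, percentile 2.0, with Lyz2 as the median gene here and among the macrophage markers), the prostaglandin synthase gene Ptgs2 was higher (1.19, or 0.78 as the median over its probe sets) and the NADPH oxidase subunit gene Ncf1 lower (-1.37, or -0.89 as that median, with 1 of its 3 probe sets higher). Acod1 had a log2 ratio of -0.96 and the inducible nitric oxide synthase gene Nos2 one of -0.43. The inflammasome list had a median of -0.32 (percentile 0.45; -0.05 and none past 2-fold under equal macrophage markers), with Panx1 at least 2-fold lower (-1.15) and Mefv (-0.74) and Nlrp3 (-0.69) short of it. In antigen presentation and co-stimulation, Icosl was at least 2.47-fold lower, Tap2 (-0.94) and Tap1 (-0.92) were short of 2-fold, and Cd83 had a log2 ratio of 0.79. The median of those 19 genes was -0.16 (percentile 24.1) and turned to 0.09 under equal macrophage markers and 0.04 with the median over probe sets.

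Genes of the pathway that makes and uses isoprenoids differed little. None of 20 cholesterol biosynthesis genes and SREBP2 targets passed 2-fold (1 was higher under equal macrophage markers), and their median of 0.05 (percentile 65.5) became -0.11 with arrays divided by their medians and -0.02 after quantile normalization. Fdps, which makes farnesyl diphosphate, had a log2 ratio of 0.92, Sc5d 0.57, Sqle 0.51 and Mvd -0.27. None of 18 prenyl transfer and isoprenoid genes passed 2-fold either, though their median of -0.29 was low (percentile 0.49); it was -0.02 under equal macrophage markers. Fnta, the shared alpha subunit of farnesyl- and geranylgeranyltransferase, had a log2 ratio of -0.77, Dolk -0.53 and Chml -0.51.

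Small GTPases, many of which carry a prenyl anchor, differed in both directions. Rhoj (3.36) and Rnd1 (3.00) were higher, and Rhob (-1.83) and Rhoh (-1.09) were at least 2-fold lower, while Rac1 had a log2 ratio of -0.35. Among 29 Ras and Rab genes, Rras2 (2.56) and Mras (1.90) were higher and none was 2-fold lower; Rap2a had a log2 ratio of -0.78. Their median of -0.02 (percentile 85.2) was 0.01 after quantile normalization, 0.03 after lowess and 0.23 under equal macrophage markers. In the PI3K and AKT pathway, Foxo3 was the only 1 of 22 genes past 2-fold (-1.49, but -0.44 as the median over its probe sets). Pik3r5 had a log2 ratio of -0.74, and the list's median of -0.16 (percentile 10.8) became 0.11 under equal macrophage markers.

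**Figure D2:**
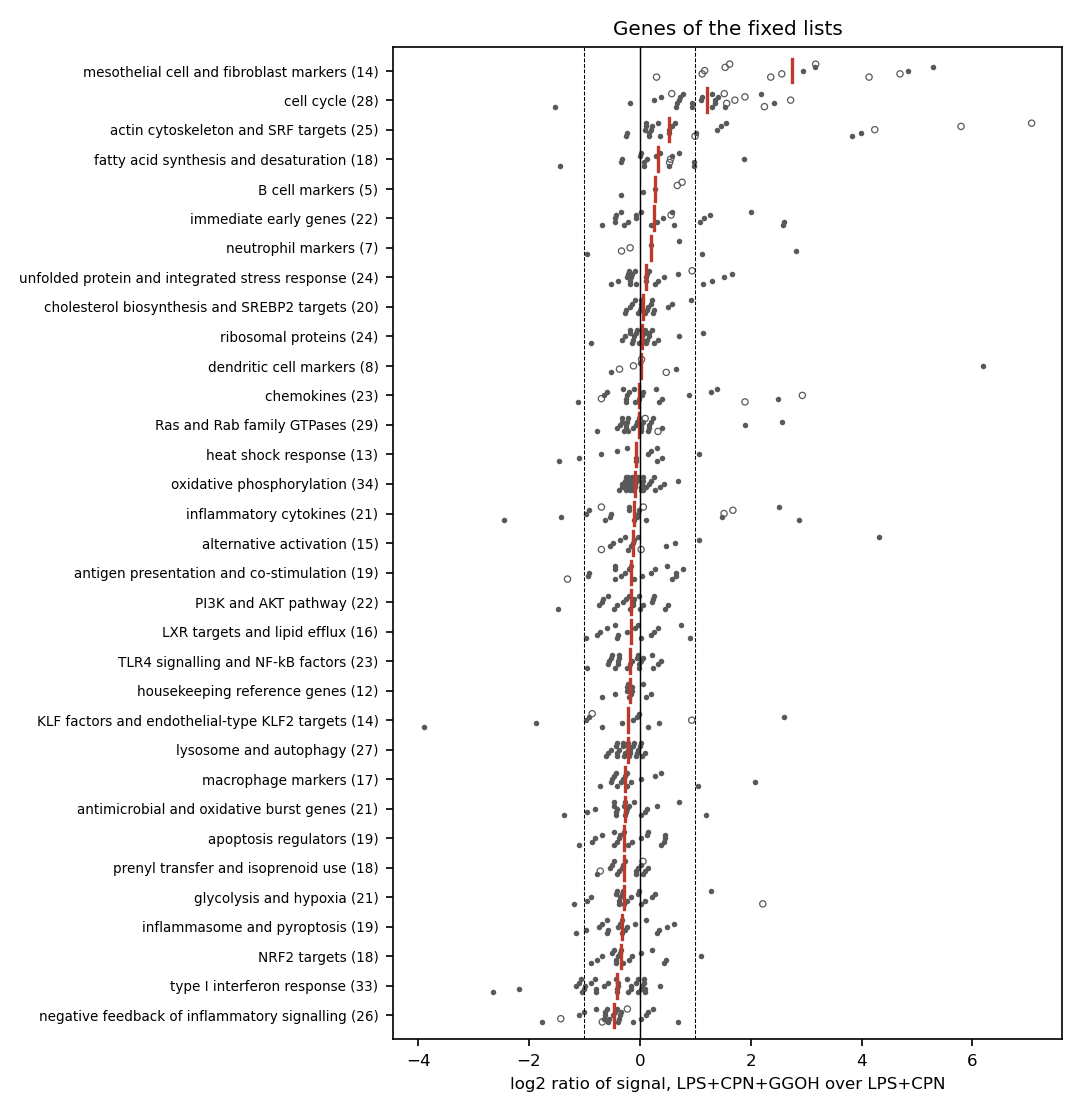
Log2 ratio of signal, LPS+CPN+GGOH over LPS+CPN (x axis), for every measured gene of 33 gene lists (y axis, number of measured genes in brackets), with bounds as open circles, medians as red bars and 2-fold differences as dashed lines. The mesothelial cell and fibroblast markers (median 2.75), cell cycle genes (1.21) and actin genes (0.52) lie to the right, and negative feedback (-0.46) and interferon genes (-0.41) lie farthest to the left.

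Cell cycle genes were higher as a group, with 16 of 28 at least 2-fold higher and a median of 1.21 (percentile 100). Examples were Ube2c (at least 6.59-fold), Top2a (log2 ratio 2.43), Rrm2 (at least 4.75-fold) and the cyclin gene Ccna2 (2.18). The cyclin gene Ccne1 was lower (-1.54). Signals of this list were low, and with the floor at the 75th percentile 16 genes were measured, of which 3 were at least 2-fold higher. Fibroblast markers were higher on the same array.

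Immediate early genes had a median of 0.25 (percentile 99.9), with 6 of 22 at least 2-fold higher and none lower. They were Gadd45a (2.60), Egr1 (2.58), Myc (2.01), Btg2 (1.26), Nr4a2 (1.16) and Fosl2 (1.09), and 4 passed 2-fold with arrays divided by their medians. In the unfolded protein and integrated stress response, Chac1 (1.67), Psat1 (1.52), Ddit4 (1.29) and Asns (1.15) were higher and none of 24 genes was 2-fold lower. That list's median of 0.12 (percentile 99.1) turned to -0.05 with arrays divided by their medians. Of 13 heat shock genes, Hspa1b (-1.45) and Hspa1a (-1.11) were at least 2-fold lower and Hspb1 was higher (1.06). Their median of -0.07 (percentile 64.5) was 0.00146 after quantile normalization, 0.04 after lowess and 0.20 under equal macrophage markers.

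NRF2 targets had a median of -0.35 (percentile 0.25; -0.08 under equal macrophage markers), with Gsr (-0.88), Gclm (-0.78) and Gclc (-0.68) short of 2-fold and the metallothionein gene Mt2 higher (1.10). Apoptosis regulators had a median of -0.28 (percentile 1.18), which turned to 0.02 under equal macrophage markers. Birc3 was the only 1 of 19 past 2-fold (-1.10), with 1 of its 2 probe sets higher, and Bcl2l11 had a log2 ratio of -0.86. In glycolysis and hypoxia, Adm (at least 4.65-fold) and Vegfa (1.28) were higher and Ankrd37 was lower (-1.20). Hk2 had a log2 ratio of -0.95, and the median of the 21 genes was -0.30 (percentile 0.78), or -0.03 under equal macrophage markers.

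In lipid metabolism, 18 fatty acid synthesis and desaturation genes had a median of 0.32 (percentile 99.1), with the desaturase gene Scd2 higher (1.88) and Acss2 lower (-1.44). Acsl4 (0.98) and Fads1 (0.97) were short of 2-fold, and the number of genes higher was 2 after quantile normalization or lowess and 3 under equal macrophage markers or with the median over probe sets. At the deposited scaling none of 16 LXR targets and lipid efflux genes passed 2-fold; 1 was lower under each of the planned scalings and 2 were higher under equal macrophage markers. Mylip had a log2 ratio of -0.97, Lpcat3 0.90 and Abca1 0.74, and the median of -0.16 (percentile 22.4) became 0.11 under equal macrophage markers.

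Lists of general cell functions stayed near 0. None of 34 oxidative phosphorylation genes passed 2-fold, and their median of -0.09 (percentile 73.0) was 0.02 after lowess and 0.18 under equal macrophage markers. Of 24 ribosomal protein genes, Rpl12 was higher (1.13); the median of 0.04 (percentile 99.1) was -0.12 with arrays divided by their medians and -0.08 with _x_at probe sets kept. None of 27 lysosome and autophagy genes passed 2-fold, and Gpnmb, at a signal of 54110 with LPS+CPN, had a log2 ratio of -0.61. Their median of -0.22 (percentile 8.03) and that of 12 housekeeping genes (-0.18, percentile 29.6, none past 2-fold) became 0.05 and 0.09 under equal macrophage markers.

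Markers of the main cell type were bright on both arrays. Lyz2 had signals of 38747 with LPS+CPN and 32153 with GGOH, Cd68 30430 and 30828, and Csf1r 21459 and 15170. The 17 measured macrophage markers had that median of -0.27 (percentile 3.59), which the added scaling sets to 0; none was 2-fold lower, and Gata6 (2.08) and Itgam (1.05) were higher. In the neutrophil list, the matrix metalloproteinase genes Mmp9 (2.82) and Mmp8 (1.12) were higher while S100a8 had a log2 ratio of -0.95. The median of those 7 genes was 0.19 (percentile 85.7), but -0.30 with the floor at the 25th percentile and -0.08 with a pseudocount. Fscn1 was the only 1 of 8 dendritic cell markers past 2-fold, and Itgax had a log2 ratio of -0.52. That list's median of 0.01 (percentile 49.1) was -0.17 with arrays divided by their medians, -0.21 after quantile normalization and -0.07 after lowess. The 5 measured B cell markers had a median of 0.27 (percentile 64.7), with none past 2-fold. Thy1 (at least 1.76-fold higher) was the only T and NK cell marker measured and Gata2 (0.51) the only mast cell marker, and 0 eosinophil and 0 erythroid markers were measured.

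Of the 34 summarised lists, 15 had a median in the outer 2.5% of random lists on either side. Lists of independently drawn genes would give 1.7. That number is no measure of chance here, because some lists share genes and the genes of a list can vary together. The small counts within lists also moved with the scaling. With arrays divided by their medians the number of genes at least 2-fold lower was 3 in antigen presentation and in glycolysis, 2 in the inflammasome, antimicrobial and apoptosis lists, and 1 in the TLR4, NRF2, ribosomal and neutrophil lists. Under each planned scaling 1 macrophage marker and 1 alternative activation gene were at least 2-fold higher. The arrays also differed in the relation of 3' to 5' signal. The 3' over 5' signal ratio of the Actb control probe sets was 2.44 with LPS+CPN and 1.24 with GGOH, and that of Gapdh was 1.98 and 0.956. The log2 ratio between arrays for Actb was 0.92 at the 5' end and -0.05 at the 3' end, and for Gapdh 0.76 and -0.29. The 18 probe sets of spiked hybridization controls had a median log2 ratio of -0.18 (SD 0.13), and the 27 Bacillus control probe sets had signals of at most 32.3. With 1 array per condition, treatment, cell content and RNA quality differ together, and no difference has a replicate check.

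**Figure D3:**
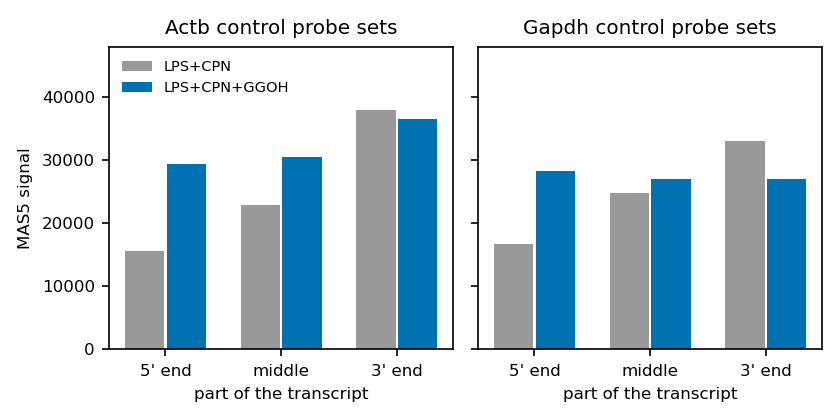
MAS5 signal (y axis) of the control probe sets at the 5' end, middle and 3' end of the Actb and Gapdh transcripts (x axis), with 1 bar per array. On the LPS+CPN array the signal is 2.44 times (Actb) and 1.98 times (Gapdh) higher at the 3' end than at the 5' end, against 1.24 and 0.956 times on the LPS+CPN+GGOH array.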

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

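Tests chosen only after the result was seen were the comparison of the marker list with the highest random list, the comparison of cell cycle with marker genes, and the decision to set aside the test on the lowest probe set. Each SE here is over the genes of a list, not over replicates.

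Signal differences also appeared in probe sets outside the gene comparison. Of 3628 measured probe sets with no or several listed genes, 240 were at least 2-fold higher with GGOH (6.62%) and 68 were lower (1.87%).

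Mesothelial cell and fibroblast markers were higher on the LPS+CPN+GGOH array (13 of 14 genes, median log2 ratio 2.75, SE 0.52). A gain of all dim probe sets is argued against by 40 genes of unrelated lineages. Their median without the floor was -0.22 (SE 0.33), against 3.16 for the markers. Poorer 5' signal on the LPS+CPN array stays open, as the whole cause or a part of it. The marker median lay above the highest median of the matched random lists, 1.16, but this was known when that test was chosen. Those lists were matched on signal and not on probe position, so the test decides nothing. The test planned for 5' signal, the median of the lowest probe set ratio per marker gene, gave 0.30, on the side that explanation predicted. However, all 7 of those probe sets were bounds at the floor, and the test was judged uninformative only once this was seen. More fibroblasts and mesothelial cells in that culture is a candidate explanation: a further list of fibroblast genes had a median of 1.32 with 14 of 22 genes higher (1.31 without Serpinh1, whose value was already known), Col1a2 reached a signal of 11165 and Sparc 9006, and no sort is named in the labels, though Lox (-0.16) and Mmp14 (0.12) were bright and near equal on both arrays. An effect of GGOH on these genes, in macrophages or in other cells, was not tested, since the design has 1 culture per treatment.

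In the interferon, cytokine and feedback lists 13 members were at least 2-fold lower on the same array, while 5 cytokine genes were at least 2-fold higher. Dilution of macrophage RNA by other cells, as the only source of these 2-fold differences, is argued against. A list of 38 further leukocyte and macrophage genes had a median of -0.18 (SE 0.09) at the deposited scaling, a loss of 11.8% where 50% would be needed. The 13 were picked for passing 2-fold, at log2 ratios up to -1.003, and single ratios carry error (SD 0.45 between probe sets). Dilution together with such error was not tested and stays open for members near 2-fold. Scaling to equal macrophage markers left 6 genes of these lists at least 2-fold lower, since it adds 0.27 to every ratio and the 13 had a median of -1.16; Ifit1, for example, went from -1.16 to -0.89. For the interferon list as a whole dilution cannot be told apart from another cause, because its median lay only -0.22 (SE 0.17) from that of the leukocyte genes. An effect of GGOH on LPS-induced genes stays among the open explanations and was not tested, for want of an array without CPN or a replicate.

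Cell cycle genes were higher with GGOH (16 of 28, median 1.21). A few noisy dim probe sets are argued against by a further list of cell cycle genes. Of its 37 measured genes 13 were higher and none lower, with a median of 0.80 (percentile 100). The absence of lower genes says little, because 15 of the 37 were at the floor on the LPS+CPN array and could only be higher. Ratios were above 0 for 32 of the 37, but the brightest, Cdt1 and Smc4, had log2 ratios of -0.18 and -0.58. Division of fibroblasts and mesothelial cells cannot be told apart from division of macrophages: the cell cycle median lay -1.55 (SE 0.55) from that of the markers, but this order was known when the test was chosen, so it decides nothing. An effect of GGOH on proliferation was not tested beyond this comparison.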

How the results depend on the processing

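The scaling to equal macrophage markers was chosen after the data were seen, and the other 8 alternatives were planned. The number of genes at least 2-fold higher was 634 and became 1658 and 126 with floors at the 25th and 75th percentiles and 991 under equal macrophage markers. The number lower was 191 and became 332 with arrays divided by their medians, 307 after quantile normalization, 1127 and 88 with the lower and higher floor, and 83 under equal macrophage markers. A higher floor leaves fewer genes to count and a lower floor more, by construction. Division by array medians and scaling to equal macrophage markers multiply whole arrays by a constant. The log2 ratios of genes measured with and without them shifted by a median of -0.17 and 0.27, in that order. Such shifts move the higher and lower counts in opposite directions. For quantile normalization the cause was not tested. Of 634 higher genes, 529, 499, 590 and 634 were also higher under array medians, quantile normalization, lowess and equal macrophage markers, and of 191 lower genes 191, 188, 186 and 83 were also lower. Among lists whose median lay in the outer 2.5% of random lists on either side, some medians turned sign. With array medians, the unfolded protein and integrated stress response went from 0.12 to -0.051 and ribosomal proteins from 0.04 to -0.12. The shift of -0.17 under that scaling accounts for both. The ribosomal median was also negative with _x_at probe sets kept (-0.0793). That of apoptosis regulators was 0.0244 under equal macrophage markers. The number of measured ribosomal genes went from 24 to 30 with _x_at probe sets kept. For apoptosis regulators it went from 19 to 20 under equal macrophage markers, which shifts ratios by 0.27. How far these steps account for the last sign changes was not tested. The cell cycle median moved to 0.50 and the mesothelial and fibroblast median to 2.05 with the higher floor, which caps ratios of dim genes, and the latter to 2.15 with a pseudocount, which shrinks them. The neutrophil median moved to -0.30 with the lower floor, under which 11 genes of the list were measured in place of 7. The cause was not tested further. Among the 156 named genes, 0 of those at least 2-fold apart at the deposited scaling turned sign. Array medians, equal macrophage markers, changed floors and the pseudocount cannot turn the sign of a 2-fold ratio, so for them that 0 was fixed in advance. Sign changes of smaller ratios were not counted. Of all 156, 17 moved with the lower floor and 34 with the higher floor (95 held, and 17 no longer passed 2-fold). With a pseudocount 22 moved, with the median over probe sets 19, with _x_at probe sets kept 3, and under the scalings 0. For array medians and equal macrophage markers this 0 was fixed in advance, since their shifts of -0.17 and 0.27 are smaller than the SD of 0.45. Under array medians 7 named genes no longer passed 2-fold, and under equal macrophage markers 9. Signal over background limits dim genes: 51.0% of probe sets on the LPS+CPN+GGOH array and 49.0% on the other were above the floor. No paired analysis was possible because each group has 1 array.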

Other observations

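The lists described here were written after the main comparison was seen but before their medians were computed, and 2 mesothelial genes (Wt1 and Slpi) had values already seen. In this part, the scaling to equal macrophage markers was chosen after the result was seen. The comparison of the interferon-gamma-type list with leukocyte genes was not among the tests written in advance.

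Targets of the transcriptional regulators YAP and TEAD, of which Ccn1 and Ccn2 were already described, were higher as a list with GGOH. Of 18 further targets 10 were at least 2-fold higher, none was 2-fold lower, and the median log2 ratio was 1.22 (percentile 100). Amotl2 (2.54) and Amotl1 (2.44), which encode angiomotin-like proteins, were measured on both arrays, Ankrd1 was at least 5.34-fold higher, and the tissue factor gene F3 was at least 4.03-fold higher. Nuak2 had a log2 ratio of -0.80. These genes moved together with fibroblast markers on the same array. Among 10 further mesothelial genes, 6 were higher, with a median of 1.69 (percentile 100), which was 1.69 over the 8 genes without Wt1 and Slpi; Cav1 had a log2 ratio of 1.75 and Aldh1a2 one of 1.64. Among genes of unrelated lineages 5 were above the floor, with a median of 0.19 (percentile 55.1) and Esam higher (1.69).

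The lower signal of Gbp7 and Ifi47 raised the hypothesis that genes of the interferon-gamma type were lower more widely. A list of 20 such genes, of which 11 were measured, had a median of -0.75 (percentile 0), and all 11 measured genes had ratios below 0. This median lay below that of the type I interferon list. However, the type I list itself holds Ifi47 and genes of the Gbp family, so the order of the medians does not separate the interferon types. Gbp8 (-1.24), Parp9 (-1.16) and Batf2 (-1.14) were at least 2-fold lower. Under equal macrophage markers 0 genes passed 2-fold, Gbp8 had a log2 ratio of -0.97, and the median was -0.48 with all 11 still below 0; no other setting was run for this list, and the other lists of this part were run at the deposited scaling alone. The median lay -0.57 from that of further leukocyte and macrophage genes (SE 0.15, over genes that can vary together and not over replicates). The median of those leukocyte and macrophage genes had percentile 15.8, and 0 of 38 passed 2-fold. These values go with a wider decrease in this gene group on the LPS+CPN+GGOH array. Such a decrease may come from the treatment or from another difference between these cultures.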
